A study of Rattus norvegicus with 6 samples.

How the data were processed

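The samples were 6 poly(A)-selected, directional RNA-seq libraries from the amygdala of Sprague Dawley rats labelled male and aged 38 postnatal days, 3 labelled as behaviourally tested (B-CTRL) and 3 labelled as not tested (NB-CTRL). Values were FPKM (fragments per unit of transcript length and of mapped fragments) made by the authors, per the file headers, with 1 column per library. The submitters' processing notes name STAR 2.5.4b, Cuffdiff 2.2.1 and genome build rn6 and give no settings, and the annotation release, read filters and lane of each library are not given in the sources used here. FPKM sums were 579141, 641725 and 583803 in B-CTRL 1, 2 and 3 and 536937, 522422 and 527081 in NB-CTRL 1, 2 and 3. Each B-CTRL sum thus lay above each NB-CTRL sum. The share of the sum in the 10 highest features was also higher in B-CTRL (7.02%, 6.16% and 6.07% against 5.32%, 4.42% and 4.20%). The values were used as deposited. The values hold no counts, so absolute depth and counting intervals are unknown. Relative depth was estimated from features below 1 FPKM, at 0 in at least 2 libraries, as the most frequent ratio to NB-CTRL 1. Between 32.6% and 44.9% of 127 to 353 such features per library lay within 0.05 log2 of that ratio, so the estimate is rough.

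From these values log2(FPKM + 0.5) was computed, and features with a mean of at least 0.5 FPKM over the 6 libraries were kept (14043 of 32662). Fold changes are on this scale, which understates the change of low genes. Groups were compared with limma 3.58.1 in R 4.3.3, 2-sided and with an intensity trend, B-CTRL minus NB-CTRL, without covariates, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The fit had 4 residual degrees of freedom and a prior of 2.97, and the median standard error was 0.20 log2. An exact permutation test of 3 against 3 cannot go below 0.1, so none is given for single genes.

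Gene lists were tested with camera with a preset correlation of 0.01, adjusted over 21 functional lists and over 17 marker lists separately, with camera with an estimated correlation and fry beside it. fry tests whether the genes of a list move one way on balance and does not compare them with other genes. With the estimated correlation 0 of 21 and 0 of 17 lists passed (lowest adjusted p 0.503 and 0.834), and with fry 0 and 0 (lowest 0.200 and 0.624). The functional lists were immediate early genes, delayed activity-regulated genes, ionotropic and metabotropic glutamate receptors, GABA genes, the endocannabinoid, opioid, oxytocin and vasopressin, dopamine and cholinergic systems, serotonin and noradrenaline receptors, neuropeptides, neuropeptide and stress hormone receptors, glucocorticoid-induced genes, synaptic vesicle genes, postsynaptic genes, oxidative phosphorylation, ribosomal proteins, heat shock and folding genes, clock genes, and interferon and inflammation genes. The marker lists covered neurons, glia, vessels, choroid plexus, ependyma, meninges, blood, and neurons of striatum, hippocampus, hypothalamus, thalamus and the amygdala's own nuclei. Some genes stand in more than 1 list. Of 747 symbols written, 23 matched no feature and 12 matched through a synonym in a RefSeq gene table of assembly GRCr8, which was used for names only.

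Groups, lists, tests and the rule for named genes were fixed before the data were examined. The rule took genes past the threshold with the largest change, or, as fewer than 10 passed, the 10 with the lowest p in each direction with a mean of at least 1 FPKM in a group, the 10 immediate early genes with the highest mean, and up to 4 members of each other list with the lowest p. Genes named outside the rule are said to be so. Coordinates are those of the file, in rn6. Of the tested features 3026 had the same locus as another feature, and their values are uncertain.

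The scripts were tested on simulated data made from the spread of these libraries. Of 200 changed genes among 14043, 48% of those changed 2-fold and 82% of those changed 4-fold were called, with 4 false calls, and a list of 47 genes shifted by 0.5 log2 gave a camera p of 6.17e-26 against 0.256 for a list that was not shifted. The changed genes were drawn from features with higher means, so these shares do not hold for low genes. Each gene was simulated independently, while the real lists had estimated correlations such as 0.372 for immediate early genes and 0.757 for ribosomal proteins. The simulation therefore does not show how often camera with its preset correlation calls a list falsely here. The alternatives chosen together with the tests were pseudocounts of 0.1 and 1, no filter, a filter of 1 FPKM, median scaling, quantile normalization, no trend, robust moderation, library weights, the replicate number as a block, leaving out each library, and other thresholds. Alternatives added after seeing the data were removal of each library's trend with locus length (loess, span 0.5), leaving out features with small RNA names or those of some other non-coding RNA families (uc_338 among them), and the striatal and the excitatory marker score as covariates. A check of length on a list is called void where under 80% of its members have a locus of their own.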

Results

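The data were transcript levels in the amygdala of Sprague Dawley rats, an outbred laboratory strain, labelled male and aged 38 postnatal days. RNA came from 3 libraries of rats that had gone through behavioural testing for social play (B-CTRL) and 3 libraries of rats that had not (NB-CTRL). The deposited table gave 1 FPKM value per feature and library for 32662 features, of which 13558 were listed at 0 in all 6 libraries and 14043 were tested. Fragment counts were not used here, so the depth of each library is unknown in absolute terms. From the steps between low values, depth relative to NB-CTRL 1 was estimated as 1.11, 0.738 and 1.36 for B-CTRL 1, 2 and 3 and as 1.62 and 1.60 for NB-CTRL 2 and 3, so B-CTRL 2 was the shallowest. The labels name separate samples of each group and do not state that each is a separate animal, so p-values measure the spread between these samples. The 13 mitochondrially encoded features were listed at 0 in all 6 libraries, so a 0 in this table can be a failed estimate.

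The comparison asked which amygdala transcripts differ between rats tested for social play and untested rats. Immediate early genes, which are transcribed within minutes of neuronal activation, were mostly higher in B-CTRL on average, with overlap between libraries. Of these genes 36 of 47 measured members had a higher mean in B-CTRL, with a median log2 difference of 0.27 (quartiles 0.047 and 0.60). Fos, an AP-1 transcription factor subunit, stood at 16.0 ± 8.52 against 6.48 ± 2.05 FPKM, log2 difference 1.17 ± 0.39 SE (levels are mean ± SD, n = 3 per group, B-CTRL first, throughout). The phosphatase gene Dusp1 stood at 29.4 ± 7.82 against 13.7 ± 4.11 FPKM, log2 difference 1.09 ± 0.27 SE. The synaptic activity gene Arc stood at 62.2 ± 46.5 against 24.0 ± 11.8 FPKM, log2 difference 1.25 ± 0.57 SE. Npas4, an activity-dependent transcription factor, stood at 6.44 ± 4.18 against 2.36 ± 1.503 FPKM, log2 difference 1.24 ± 0.50 SE. These genes had the largest log2 differences of the list, and all but Arc were named after their values were seen. The list passed camera, limma's competitive gene set test (adjusted p = 0.00188), and did not pass with its own correlation (adjusted p = 0.538 with an estimated correlation).

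Of the 47 immediate early genes, 8 had an unadjusted limma p under 0.05, all higher in B-CTRL, and 0 passed over all genes or adjusted over the list alone. These 8, named after their values were seen, were Apold1 (0.80 ± 0.20 log2 ± SE), Dusp1, Btg2 (0.86 ± 0.25), Gadd45g (0.72 ± 0.22), Dusp5 (0.92 ± 0.30), Fos, Gadd45b (0.38 ± 0.14) and Npas4. Among the 10 members with the highest mean FPKM, Arc, Plk2 (0.37 ± 0.33), Rgs2 (0.47 ± 0.26), Jund (0.23 ± 0.17), Nr4a1 (0.83 ± 0.56), Junb (0.77 ± 0.37) and Egr1 (0.34 ± 0.48) had positive differences. Homer1 (-0.20 ± 0.41), Egr3 (0.038 ± 0.44), Srf (-0.028 ± 0.27) and Egr1 lay within 1 standard error of 0. The sign of each of these 4 turned when some library was left out, and that of Egr3 also with library weights (-0.21). Fos lies at chromosome 6, 109300432 to 109303299 (ENSRNOG00000008015) in build rn6, as the file gives it. In the same build Dusp1 lies at chromosome 10, 16970625 to 16973418 (ENSRNOG00000003977), and Arc at chromosome 7, 115907096 to 115910541 (ENSRNOG00000043465). B-CTRL 3 held the highest value of Fos (25.8 FPKM), Arc (116 FPKM) and Npas4 (11.2 FPKM). The striatal genes Drd1 and Drd2, named after their values were seen, were also highest there (156 and 163 FPKM). The list's score in a library, the mean log2 deviation of its members from their 6-library means, was -0.0060, -0.10 and 0.59 in B-CTRL 1, 2 and 3 and -0.081, -0.55 and 0.15 in NB-CTRL 1, 2 and 3, so NB-CTRL 3 lay above B-CTRL 1 and 2. Without B-CTRL 3 the list's median was 0.17 (adjusted p = 0.27) and without NB-CTRL 2 it was 0.14 (adjusted p = 0.0999). Without B-CTRL 2 it was 0.41 and without NB-CTRL 3 it was 0.50. Removing each library's trend with locus length, a setting chosen after seeing the data, gave a median of 0.22 (adjusted p = 0.0883).

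**Figure D1:**
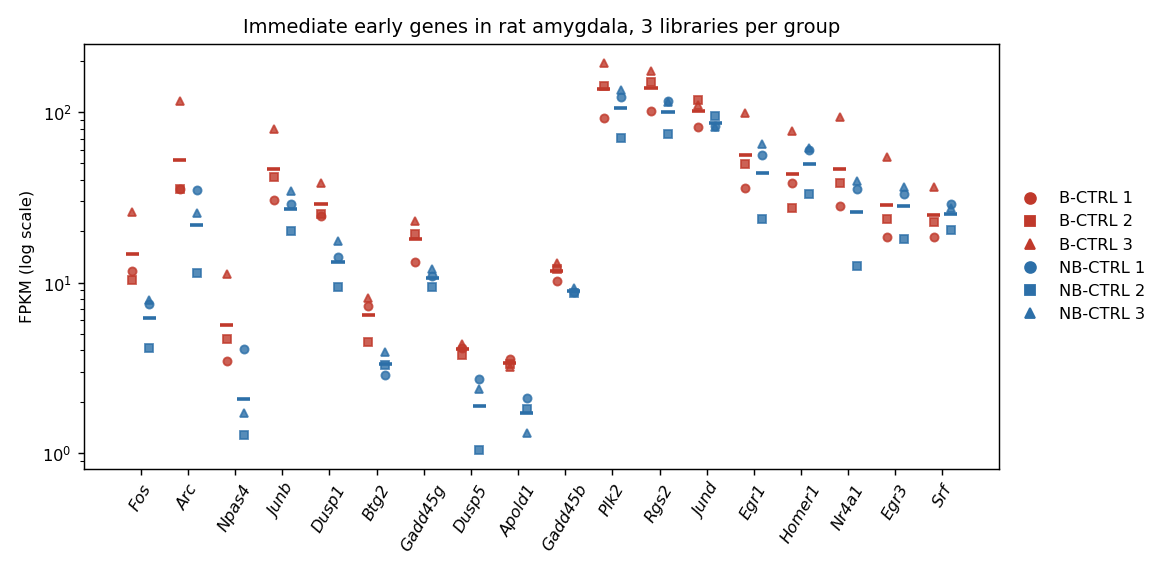
FPKM on a log scale of 18 immediate early genes in the 3 B-CTRL (red) and 3 NB-CTRL (blue) libraries, with each point a library and each bar the geometric mean of a group. The genes are the 8 with an unadjusted limma p under 0.05, picked after their values were seen, and the 10 with the highest mean FPKM. Fos lies between 10.4 and 25.8 FPKM in B-CTRL and between 4.12 and 7.85 FPKM in NB-CTRL, while Egr3 and Srf overlap.

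Transcripts for cytosolic ribosomal proteins and for oxidative phosphorylation were higher in B-CTRL on average. Of 47 measured cytosolic ribosomal protein genes, 46 had a higher mean in B-CTRL, with a median log2 difference of 0.53 (quartiles 0.47 and 0.58). Rpl28 stood at 144 ± 14.1 against 95.9 ± 3.02 FPKM, log2 difference 0.58 ± 0.12 SE. Rps15 stood at 822 ± 126 against 534 ± 43.3 FPKM, log2 difference 0.61 ± 0.16 SE. Of 39 measured nuclear genes for oxidative phosphorylation, the pathway that makes ATP in mitochondria, 38 were higher, with a median of 0.40 (quartiles 0.27 and 0.50). Ndufb9, a subunit of respiratory complex I, stood at 519 ± 68.2 against 367 ± 10.1 FPKM, log2 difference 0.49 ± 0.14 SE. Ndufb3, another, stood at 189.9 ± 40.3 against 124 ± 1.85 FPKM, log2 difference 0.59 ± 0.16 SE. Cox7c, a subunit of complex IV whose locus is shared with another feature, stood at 1306 ± 304 against 810.2 ± 47.5 FPKM, log2 difference 0.67 ± 0.19 SE.

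In the ribosomal list 40 genes passed limma adjusted over the list alone and 0 over all genes. Its members moved together (estimated correlation 0.757), so these 40 do not count as separate differences. In the oxidative phosphorylation list 22 had an unadjusted p under 0.05 and 0 passed adjusted over the list alone. Both lists passed camera (adjusted p = 5e-21 and 2.84e-14). Neither passed with its own correlation (adjusted p = 0.503 and 0.503 with an estimated correlation). Each B-CTRL library had a higher mean of each list than each NB-CTRL library. FPKM sums were also higher in each B-CTRL than in each NB-CTRL library. Quantile normalization lowered the medians to 0.23 and 0.16, with both lists still past camera. Ribosomal protein genes have many near-identical pseudogenes, and 63.8% of the ribosomal and 74.4% of the oxidative phosphorylation members had a locus of their own in the table, so single values here are uncertain. B-CTRL 2, the library with the highest mean of both lists, also had the strongest trend with locus length. Among features with their own locus, those in the longest eighth of loci lay -0.34 there and those in the shortest eighth 0.20 from their gene means (median log2). The longest minus the shortest was 0.022, -0.53 and -0.046 in B-CTRL 1, 2 and 3 and 0.17, 0.18 and 0.23 in NB-CTRL 1, 2 and 3. The trend thus differed between the groups in each library, so leaving out B-CTRL 2 does not remove it.

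**Figure D2:**
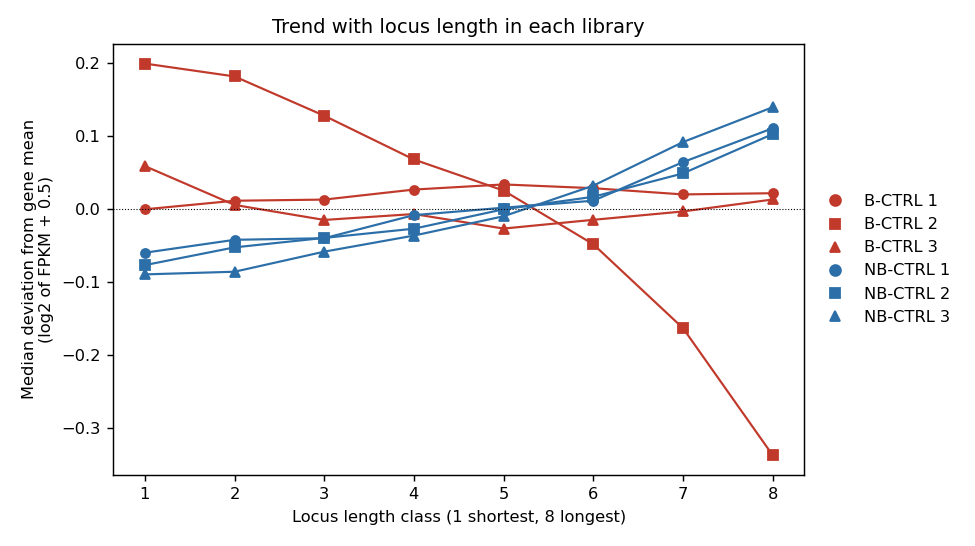
Median deviation of features with their own locus from their 6-library mean (log2 of FPKM + 0.5) in 8 classes of locus length, for each library. B-CTRL 2 runs from 0.20 in the shortest to -0.34 in the longest class, and the 3 NB-CTRL libraries run the other way, ending between 0.10 and 0.14.

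Synaptic gene groups were lower in B-CTRL on average, and the libraries of the groups overlapped in 3 of 5 lists. Features with long loci were lower in general too, as given below. Of 22 AMPA, NMDA and kainate receptor subunits and associated genes, which carry fast glutamate transmission, 18 were lower, with a median log2 difference of -0.36. Grin2d stood at 2.77 ± 0.571 against 7.36 ± 3.38 FPKM, log2 difference -1.19 ± 0.32 SE. Grik3 stood at 7.73 ± 5.87 against 16.1 ± 2.53 FPKM, log2 difference -1.26 ± 0.50 SE. Of 22 genes for GABA synthesis, transport and reception, 18 were lower (median -0.29). The receptor subunit gene Gabrb2 stood at 18.9 ± 9.51 against 48.0 ± 13.6 FPKM, log2 difference -1.44 ± 0.44 SE. Of 30 synaptic vesicle and release genes, 24 were lower (median -0.34). The calcium sensor gene Syt2 stood at 14.3 ± 5.16 against 25.6 ± 4.68 FPKM, log2 difference -0.86 ± 0.26 SE. Sv2a stood at 126 ± 2.21 against 171 ± 32.3 FPKM, log2 difference -0.43 ± 0.15 SE. Napa, higher in B-CTRL, stood at 259 ± 40.3 against 192 ± 7.02 FPKM, log2 difference 0.41 ± 0.15 SE. Of 31 postsynaptic scaffold and CaMK genes, 24 were lower (median -0.40). The adhesion gene Nlgn2 stood at 43.7 ± 15.9 against 67.8 ± 3.68 FPKM, log2 difference -0.68 ± 0.24 SE. Camk2d stood at 36.9 ± 12.03 against 68.9 ± 23.3 FPKM, log2 difference -0.89 ± 0.32 SE. Of 29 receptors for neuropeptides and stress hormones, 23 were lower (median -0.26). The substance P receptor gene Tacr1 stood at 5.32 ± 1.22 against 8.57 ± 1.02 FPKM, log2 difference -0.66 ± 0.20 SE. The corticotropin-releasing hormone receptor gene Crhr1 stood at 5.23 ± 0.353 against 7.21 ± 1.24 FPKM, log2 difference -0.42 ± 0.17 SE.

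These 5 lists passed camera with adjusted p = 0.0103, 0.0103, 0.00488, 0.0103 and 0.0384 in that order. None passed with its own correlation (adjusted p = 0.503, 0.503, 0.503, 0.546 and 0.507 with an estimated correlation). In each of the 5 lists 0 genes passed over all genes or adjusted over the list alone. Scores of the glutamate receptor and GABA lists were lower in each B-CTRL than in each NB-CTRL library, and those of the other 3 overlapped. For vesicle genes B-CTRL 1 and 3 (0.080 and 0.050) lay above NB-CTRL 1 (-0.061). For postsynaptic genes B-CTRL 3 (0.27) lay above NB-CTRL 1 and 2 (0.19 and 0.014). For peptide receptors B-CTRL 1 (0.27) lay above NB-CTRL 1 and 3 (-0.0029 and -0.0022). Without B-CTRL 2, the library with the strongest length trend, the postsynaptic median was -0.017 (adjusted p = 0.228) and the vesicle median -0.15 (adjusted p = 0.0758). Without it the glutamate receptor median was -0.18 (adjusted p = 0.0625) and the peptide receptor median -0.17 (adjusted p = 0.143). Calls also ended for glutamate receptors without B-CTRL 1 (median -0.32, adjusted p = 0.0835), for GABA genes without NB-CTRL 2 (median -0.17, adjusted p = 0.0663) and for postsynaptic genes without NB-CTRL 3 (median -0.31, adjusted p = 0.0775). The peptide receptor call ended in 9 of 20 refits (adjusted p up to 0.323), among them those without B-CTRL 3 (median -0.21, adjusted p = 0.306) and without NB-CTRL 2 (median -0.16, adjusted p = 0.197). NB-CTRL 2 held the highest score of the GABA and peptide receptor lists (0.37 and 0.42) and also of the hypothalamic and thalamic markers (0.97, against at most 0.11 elsewhere). The medians were lower still without B-CTRL 3 for glutamate receptors (-0.55), and without B-CTRL 1 and NB-CTRL 3 for peptide receptors (-0.59 and -0.42). With quantile normalization the GABA median was -0.45. All 5 calls ended when the trend with locus length was removed, a setting chosen after seeing the data (in the order above median -0.21, adjusted p = 0.173; median -0.17, adjusted p = 0.101; median -0.20, adjusted p = 0.0555; median -0.10, adjusted p = 0.129; and median -0.23, adjusted p = 0.0788). Each median stayed below 0 and lay closer to it. The check is void for glutamate receptors, vesicle genes and GABA genes, of which 40.9%, 66.7% and 77.3% had a locus of their own. Among all features with their own locus, the longest of 8 length classes had a median log2 difference of -0.23 (quartiles -0.53 and 0.017). Median loci of the glutamate receptor, GABA and postsynaptic lists (145, 85.9 and 94.0 kb) lie in that class, so a lower level was shared with long loci in general. Those of vesicle genes (53.3 kb) and peptide receptors (26.4 kb) lie in classes with medians of -0.13 and 0.015.

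**Figure D3:**
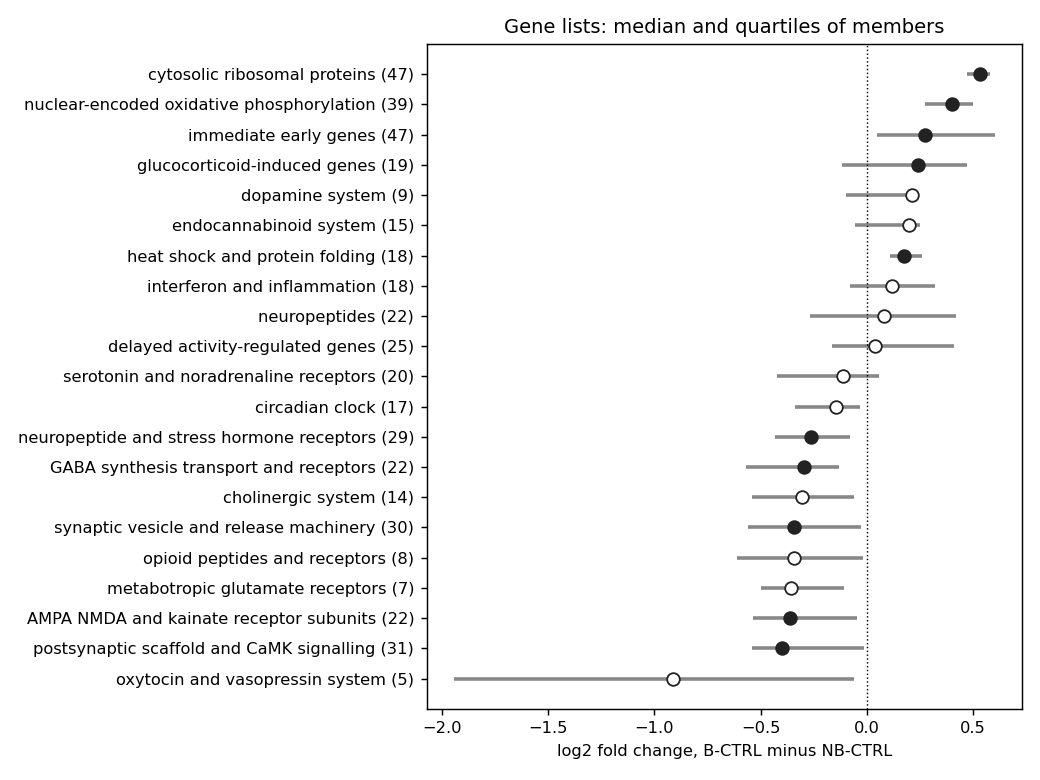
Median (point) and quartiles (bar) of the log2 fold change, B-CTRL minus NB-CTRL, over the measured members of the 21 functional gene lists, with the number of members in parentheses. Filled points are the 10 lists past camera with its preset correlation; medians run from 0.53 for ribosomal proteins to -0.91 for the oxytocin and vasopressin system.

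Glucocorticoid-induced genes and heat shock genes were higher in B-CTRL on average, by smaller steps, with overlap between libraries. Of 19 measured glucocorticoid-induced genes 13 were higher (median 0.24). Ddit4 stood at 73.4 ± 0.944 against 51.3 ± 9.60 FPKM, log2 difference 0.53 ± 0.16 SE. The kinase gene Sgk1 stood at 41.1 ± 7.62 against 25.7 ± 5.08 FPKM, log2 difference 0.67 ± 0.20 SE. The metallothionein gene Mt2A stood at 55.7 ± 17.7 against 28.6 ± 12.9 FPKM, log2 difference 1.01 ± 0.39 SE. Of 18 heat shock and protein folding genes 17 were higher (median 0.18). The small heat shock protein gene Hspb1 stood at 10.8 ± 2.00 against 7.46 ± 0.91 FPKM, log2 difference 0.50 ± 0.18 SE. Both passed camera (adjusted p = 0.0201 and 0.00662). Neither did with its own correlation (adjusted p = 0.507 and 0.503 with an estimated correlation). In limma 0 genes of either passed over all genes or adjusted over the list alone. The glucocorticoid score was 0.36, -0.010 and -0.014 in B-CTRL 1, 2 and 3 and -0.066, -0.35 and 0.087 in NB-CTRL 1, 2 and 3, so NB-CTRL 3 lay above B-CTRL 2 and 3. B-CTRL 1, the highest in both lists, is the library that held choroid plexus transcripts and almost no chromosome Y transcripts. The heat shock score of B-CTRL 3 (-0.080) lay below that of NB-CTRL 3 (-0.028). The glucocorticoid call ended without B-CTRL 1 (median 0.20, adjusted p = 0.237) and without NB-CTRL 2 (median 0.10, adjusted p = 0.147). The heat shock call ended without B-CTRL 1 (median 0.17, adjusted p = 0.0567) and under quantile normalization (median 0.060, adjusted p = 0.584). Without B-CTRL 3 the heat shock median was 0.28. Both calls also ended after removal of the length trend (median 0.18, adjusted p = 0.117 for glucocorticoid-induced and median 0.11, adjusted p = 0.129 for heat shock genes), and the glucocorticoid call with the excitatory marker score as a covariate (median 0.24, adjusted p = 0.0578). Of the heat shock members 77.8% had a locus of their own, so the length check is void for that list.

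The other 11 of 21 functional lists did not pass camera. The number of functional lists past the threshold was 10, and 6 without B-CTRL 2. Among transmitter systems, the metabotropic glutamate receptors (1 of 7 higher, median -0.36, adjusted p = 0.074) and the cholinergic system (3 of 14 higher, median -0.30, adjusted p = 0.0939) leaned lower. The opioid peptides and receptors (2 of 8 higher, median -0.34, adjusted p = 0.146) did too. The endocannabinoid system (11 of 15 higher, median 0.20, adjusted p = 0.124) leaned higher. The serotonin and noradrenaline receptors (6 of 20 higher, median -0.11, adjusted p = 0.157, and a median of 0.0016 with quantile normalization) and the circadian clock (3 of 17 higher, median -0.15, adjusted p = 0.114) lay closer to 0. The oxytocin and vasopressin system (1 of 5 higher, median -0.91, adjusted p = 0.124) was lowest on average. That median was the value of Oxtr, a low gene at 0.305 ± 0.165 against 1.04 ± 0.471 FPKM (log2 difference -0.91 ± 0.31 SE). Oxt and Avp were highest in NB-CTRL 2 (29.6 and 14.8 FPKM), and without that library the list's median was -0.40. Over 20 refits this list passed camera in 2 (lowest adjusted p = 0.0203), with medians from -1.51 to -0.062. The circadian clock passed in 5 of 20 (lowest adjusted p = 0.0101), with medians from -0.28 to -0.042. The metabotropic receptors passed in 3 of 20 and interferon and inflammation genes in 4. Delayed activity-regulated genes (14 of 25 higher, median 0.040, adjusted p = 0.431) and interferon and inflammation genes (13 of 18 higher, median 0.12, adjusted p = 0.146) were not called. For the dopamine system (6 of 9 higher, median 0.21, adjusted p = 0.945) and the neuropeptides (14 of 22 higher, median 0.081, adjusted p = 0.869) the median and the test's direction were above 0. Their means were below it (-0.0019 and -0.012), and their medians turned negative with library weights (-0.11 and -0.042).

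No single gene separated the groups after adjustment. With limma 0 of 14043 features passed an adjusted p of 0.05 (lowest 0.254). An unadjusted p under 0.05 was found for 1730 (877 higher and 853 lower in B-CTRL), where 702 would be expected by chance. Of these, 26 were at least 2-fold higher and 152 at least 2-fold lower. The groups did not overlap for 23.7% of features, where chance gives 10%. Both chance figures are averages, and other groupings of these libraries gave from 53 to 1503 genes at an unadjusted limma p under 0.05. The excess over them is therefore not a test of the groups. The number of genes at unadjusted p under 0.05 was 3644 without B-CTRL 3, and 815, 516 and 854 without NB-CTRL 1, 2 and 3. Without NB-CTRL 3 the small RNA feature SNORA70 passed (adjusted p = 0.0321), named after its value was seen. Of the 10 features with the lowest p in each direction, none of which passed, the protein-coding Anxa4, a phospholipid-binding annexin, stood at 13.3 ± 2.25 against 4.75 ± 1.11 FPKM, log2 difference 1.40 ± 0.21 SE. Lxn stood at 38.2 ± 6.22 against 21.4 ± 2.46 FPKM, log2 difference 0.82 ± 0.16 SE. Rpl17 stood at 482 ± 107 against 249 ± 8.33 FPKM, log2 difference 0.93 ± 0.17 SE. The loci of these 3 are shared with other features. Among those lower in B-CTRL, Arhgef1 stood at 12.8 ± 0.187 against 22.9 ± 2.65 FPKM, log2 difference -0.81 ± 0.14 SE. Lrrc16b stood at 8.98 ± 0.909 against 18.2 ± 3.55 FPKM, log2 difference -0.97 ± 0.18 SE. The zinc finger gene Tshz2 stood at 4.65 ± 1.26 against 11.3 ± 1.84 FPKM, log2 difference -1.21 ± 0.22 SE. The non-coding Snhg11, at a shared locus, stood at 74.9 ± 15.9 against 153 ± 17.2 FPKM, log2 difference -1.04 ± 0.18 SE. The lowest p belonged to 1 of several features named uc_338 (ENSRNOG00000058794, chromosome 9, 69953439 to 69956160), which was listed at 0 in the 3 B-CTRL libraries and at 3.20, 1.98 and 2.07 FPKM in NB-CTRL 1, 2 and 3. A feature named U2 (ENSRNOG00000057115, chromosome 1, 88819444 to 88826302) was likewise listed at 0 in B-CTRL and at 4.64, 1.43 and 1.49 FPKM in NB-CTRL. Both share their loci with other features, and U2 is the name of a small nuclear RNA, which a poly(A) library measures poorly. The other 11 of these 20 were Rpl28, described above, RNase_MRP, RGD1562378, LOC100910944, Fam229b, LOC102557117, RGD1563091, AABR07063459.1, Rn60_10_0615.5, AABR07054983.1 and Rn60_1_1004.2, with adjusted p = 0.400 each.

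Markers of 17 cell types and neighbouring regions were measured to describe what the dissected pieces held. Microglial genes were higher in B-CTRL: 12 of 14 had a higher mean (median 0.33). Tmem119 stood at 11.5 ± 2.04 against 6.68 ± 0.215 FPKM, log2 difference 0.73 ± 0.16 SE. Aif1 stood at 39.6 ± 7.67 against 26.9 ± 2.41 FPKM, log2 difference 0.54 ± 0.18 SE. Trem2 stood at 10.6 ± 1.55 against 7.69 ± 0.792 FPKM, log2 difference 0.43 ± 0.16 SE. This list passed camera (adjusted p = 0.00619). It did not pass with its own correlation (adjusted p = 0.834 with an estimated correlation), and lost its call without B-CTRL 1 (median 0.27, adjusted p = 0.0586). That library held choroid plexus transcripts and almost no chromosome Y transcripts, as given below. The microglial score was 0.26, 0.23 and -0.054 in B-CTRL 1, 2 and 3 and -0.069, -0.23 and -0.14 in NB-CTRL 1, 2 and 3. The number of marker lists past the threshold was 1, and 2, 4 and 3 without B-CTRL 1, 2 and 3, and 5 without NB-CTRL 1 or NB-CTRL 3. Tmem119 was the 1 gene of the list that passed adjusted over the list alone, and 0 passed over all genes. Oligodendrocyte genes (12 of 13 higher, median 0.44, adjusted p = 0.0825) and red blood cell genes (5 of 5 higher, median 0.36, adjusted p = 0.133) were higher on average and not called. The same held for ependymal genes (7 of 8 higher, median 0.86, adjusted p = 0.0887) and striatal projection neuron genes (14 of 17 higher, median 0.23, adjusted p = 0.311), the latter turning negative with library weights (-0.18). Without B-CTRL 1 the ependymal median was 0.078 (adjusted p = 0.27). Ependymal and oligodendrocyte genes each passed camera in 4 of 20 refits. Meningeal fibroblast genes (1 of 11 higher, median -0.28, adjusted p = 0.148) and hypothalamic and thalamic genes (3 of 14 higher, median -0.37, adjusted p = 0.148) were lower on average and not called. The same held for central and medial amygdala genes (5 of 16 higher, median -0.19, adjusted p = 0.249) and pericyte and smooth muscle genes (2 of 10 higher, median -0.13, adjusted p = 0.255). In 20 refits the striatal, meningeal and central and medial amygdala lists passed camera in 2 each, and the red blood cell and hypothalamic and thalamic lists in 1 each.

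Markers of excitatory neurons (7 of 11 higher, median 0.21, adjusted p = 0.787) and inhibitory interneurons (4 of 11 higher, median -0.13, adjusted p = 0.461) were not called. Over 20 refits the excitatory list passed camera in 1 (adjusted p = 0.0492), with medians from -0.30 to 0.61. Markers of astrocytes (6 of 12 higher, median -0.0083, adjusted p = 0.787) and endothelial cells (2 of 9 higher, median -0.092, adjusted p = 0.787) were not called. Markers of hippocampal neurons (3 of 8 higher, median -0.12, adjusted p = 0.787) and basolateral and intercalated amygdala neurons (5 of 12 higher, median -0.088, adjusted p = 0.551) were not called either. For oligodendrocyte precursors (6 of 9 higher, median 0.041, adjusted p = 0.74) the median was above 0, and the mean (-0.13) and the test's direction were below it. Choroid plexus genes (12 of 12 higher, median 1.16, adjusted p = 0.0522) were not called. Ttr, the thyroid hormone carrier that choroid plexus secretes, stood at 7142 FPKM in B-CTRL 1 and between 2.67 and 27.2 FPKM in the others. The list passed camera in 12 of 20 refits (lowest adjusted p = 5.51e-05). Without B-CTRL 1 it did not, with a median -0.039, adjusted p = 0.835.

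The library labelled B-CTRL 1 also differed in sex-linked transcripts, although all 6 libraries are labelled male. The 5 features on chromosome Y with a mean of at least 0.5 FPKM summed to 0.612 FPKM in this library and to between 89.4 and 129 FPKM in the others. Eif2s3y (ENSRNOG00000060048, chromosome Y, 914061 to 933698) stood at 0.317 FPKM there and between 49.5 and 89.9 FPKM elsewhere. A feature on chromosome X, Rn50_X_0752.3 (ENSRNOG00000051257, 74304291 to 74345507), stood at 100.9 FPKM there, at 0.22 FPKM in NB-CTRL 1, and was listed at 0 in the other 4. Of 2 other X-linked genes looked up, Ddx3x stood at 154 FPKM there against 90.3 to 100.3 FPKM elsewhere, and Kdm5c at 29.5 FPKM against 18.1 to 33.5 FPKM. Across all tested features, correlations of log2 values were 0.947 to 0.949 between B-CTRL libraries, 0.974 to 0.977 between NB-CTRL libraries and 0.941 to 0.976 between groups. The first principal component, 40.3% of the variance, set B-CTRL 2 apart, and the second, 25.9%, set B-CTRL 1 apart. The number of genes at unadjusted p under 0.05 was 1949 without B-CTRL 1 and 1236 without B-CTRL 2, and 0 features passed limma's adjusted p in either case. The sex-linked features were named after their values were seen.

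**Figure D4:**
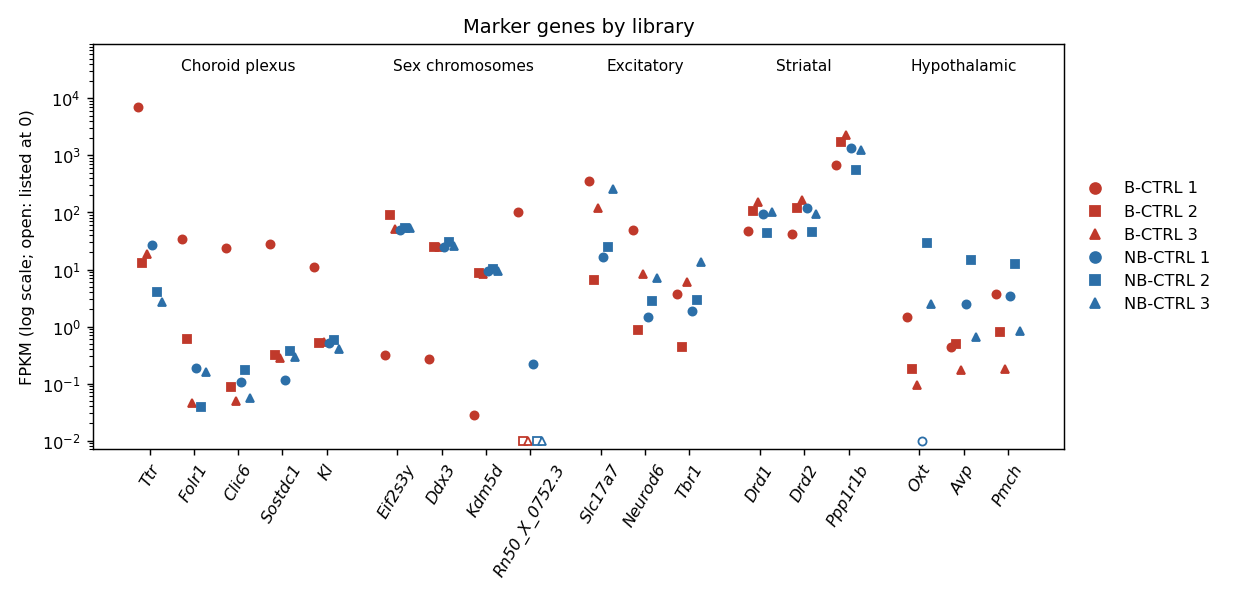
FPKM on a log scale of markers of choroid plexus, sex chromosomes, excitatory neurons, striatum and hypothalamus, with each point a library and open points drawn at the lower edge for values listed at 0. B-CTRL 1 stands apart in Ttr (7142 FPKM against at most 27.2) and in Eif2s3y (0.317 FPKM against at least 49.5), and Slc17a7 spans 6.58 to 350.5 FPKM.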

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

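Removing the trend with locus length, leaving out small RNA names and the 2 covariates were chosen after seeing the data, and the other settings were planned. The count of genes past the threshold stayed at 0 in the planned and added settings except without NB-CTRL 3, where SNORA70 passed, so leaving out 1 library gave 0 to 1. The number of genes at unadjusted p under 0.05 ran from 516 to 3644 with 1 library left out, each of which changes the number of samples, and was 2771 with the excitatory score as a covariate. Functional lists past camera numbered 10, 6 to 11 with 1 library left out, 2 after removal of the length trend, and 0 with an estimated correlation and with fry. Marker lists past camera numbered 1, with 1 to 5 when a library was left out, 2 with a pseudocount of 1, median scaling, quantile normalization or no small RNA names, 3 with a filter of 1 FPKM or library weights, 4 with the striatal score, and 0 with an estimated correlation and with fry. The immediate early list's median ran from 0.14 to 0.50 with 1 library left out, was 0.22 after removal of the length trend (adjusted p = 0.0883), and stayed at 0.27 with an estimated correlation (adjusted p = 0.538) and fry (adjusted p = 0.454), with adjusted p from 1.73e-06 to 0.27 over 20 refits. Ribosomal and oxidative phosphorylation lists passed camera in all 20 refits. Except where fewer samples were used, the cause of these moves was not tested.

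With the replicate number as a block, 0 genes passed, the number of genes at unadjusted p under 0.05 was 1463, and 4 marker lists passed. The main fit did not pair samples by number, because the labels do not say that the numbers pair animals. Deviations of libraries with the same number correlated at -0.222, 0.0719 and 0.147, and only B-CTRL 2 correlated best with its own number. As deviations were taken from group means, these correlations depend on each other and cannot decide whether samples are paired.

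Over the settings, gene list values turned sign 38 times, gained a call 43 times, lost one 52 times and were alike 703 times. Values of named genes turned sign 22 times and were alike 3572 times. With 1 library left out, medians ran -0.048 to 0.22 for delayed activity-regulated genes, -0.092 to 0.21 for dopamine, -0.20 to 0.040 for serotonin and noradrenaline receptors, -0.072 to 0.27 for neuropeptides, -0.059 to 0.29 for interferon and inflammation, -0.30 to 0.61 for excitatory neurons, -0.27 to 0.043 for interneurons, -0.054 to 0.10 for astrocytes, -0.11 to 0.18 for oligodendrocyte precursors, -0.22 to 0.082 for endothelium, -0.039 to 1.77 for choroid plexus, -0.83 to 0.047 for meninges, -0.094 to 0.77 for striatal neurons and -0.33 to 0.094 for hippocampal neurons. Log2 differences ran -0.10 to 0.66 for gene Egr1 (ENSRNOG00000019422), -0.61 to 0.13 for gene Homer1 (ENSRNOG00000047014), -0.41 to 0.35 for gene Egr3 (ENSRNOG00000017828), -0.30 to 0.18 for gene Srf (ENSRNOG00000018232), -0.34 to 0.020 for gene Pdgfra (ENSRNOG00000002244), -0.13 to 0.46 for gene Enpp6 (ENSRNOG00000009660), -0.059 to 1.82 for gene Tmem212 (ENSRNOG00000012608), -0.84 to 0.095 for gene Wfs1 (ENSRNOG00000005108) and -1.20 to 0.079 for gene Calb2 (ENSRNOG00000016977). Without a filter the dopamine median was -0.043. Quantile normalization gave 0.0016 for serotonin and noradrenaline receptors, 0.0023 for endothelium, -0.022 for gene Calr (ENSRNOG00000003029) and -0.014 for gene S100b (ENSRNOG00000001295). Library weights gave -0.11 for dopamine, -0.042 for neuropeptides, 0.015 for astrocytes, -0.18 for striatal neurons, 0.078 for hippocampal neurons, -0.21 for Egr3 and 0.039 for Pdgfra. Removal of the length trend gave -0.022 for oligodendrocyte precursors, 0.19 for basolateral and intercalated neurons, -0.075 for Egr3 and 0.18 for gene Grm7 (ENSRNOG00000005662). The striatal score gave 0.031 for astrocytes, -0.024 for striatal neurons (the genes that the score is made of) and -0.15 for Egr3, and the excitatory score 0.011 for astrocytes. None of these was called in the planned analysis, and the cause was not tested. The authors' own comparison was not used here, and random matched lists, planned for a table without library columns, were not run. Relative depth was lowest in B-CTRL 2 (0.738), which limits low genes there most.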

Other observations

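The tests of explanations in this part were chosen after the results were seen, while leaving out each library and the gene lists were planned.

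Levels of genes that mark brain regions or cell types varied widely between libraries of the same group. Slc17a7, a vesicular glutamate transporter gene in the excitatory neuron list, stood at 350.5, 6.58 and 122 FPKM in B-CTRL 1, 2 and 3. In NB-CTRL 1, 2 and 3 it stood at 16.7, 24.8 and 263 FPKM, so the range was 53.2-fold. Whether this reflects excitatory neurons of the amygdala or of cortex was not tested. Neurod6 stood at 48.6 FPKM in B-CTRL 1 and at most 8.31 FPKM elsewhere. The genes in this paragraph were chosen after their values were seen. The dopamine receptor gene Drd1 ran from 42.9 FPKM in NB-CTRL 2 to 156 FPKM in B-CTRL 3, and Adora2a from 79.1 FPKM in B-CTRL 1 to 289 FPKM in B-CTRL 3. The hypothalamic peptide genes Oxt, Avp and Pmch were highest in NB-CTRL 2 (29.6, 14.8 and 12.3 FPKM), while Hcrt stood at 3.61 FPKM in B-CTRL 1 and at most 0.151 FPKM elsewhere. Myelin genes also varied, with Mbp from 3560.0 FPKM in NB-CTRL 3 to 8286 FPKM in B-CTRL 1.

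The library labelled B-CTRL 1 lacked nearly all chromosome Y transcripts and held choroid plexus transcripts. Failed estimates are argued against for the Y-linked features, because 3 of 5 were above 0 and still far below the other libraries. RNA of a female animal may explain them, since the X-linked feature Rn50_X_0752.3, which is listed at 0 or at most 0.22 FPKM elsewhere, stood at 100.9 FPKM and the X-linked Ddx3x at 154 FPKM against at most 100.3, while the X-linked Kdm5c (29.5 FPKM) lay within the range of the others (18.1 to 33.5 FPKM); whether a tissue or label was exchanged is open. For choroid plexus, 11 of 12 measured markers were at least 4-fold above the highest other library, with Ttr at 7142, Clic6 at 24.3 and Folr1 at 33.9 FPKM, which is consistent with choroid plexus tissue in the piece. A response shared by the tested group is argued against, since the median of these markers in B-CTRL 2 and 3 against NB-CTRL was -0.0393.

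Ribosomal and oxidative phosphorylation transcripts were higher in B-CTRL on average, and postsynaptic transcripts lower, although none of these 3 lists passed with an estimated correlation (adjusted p = 0.503, 0.503 and 0.546) or with fry (adjusted p = 0.2, 0.2 and 0.49). As the whole cause of the first pair, a trend with locus length is argued against only weakly. Other features in the shortest eighth of loci had a median log2 difference of 0.126 and 0.132, below the lower quartiles of the lists (0.47 and 0.27). These features were not matched on level, and the scale used understates changes of low genes. Over all features with their own locus in that class the upper quartile was 0.377. This lay below the ribosomal lower quartile and above that of oxidative phosphorylation. A first test, the medians after removing the trend (0.41 and 0.39), was set aside as void because too few members had a locus of their own, and the length of transcripts, RNA quality and behavioural testing itself stay open. B-CTRL 2 alone is argued against for that pair, whose medians without it were 0.38 and 0.27, but it may account for the postsynaptic list, whose median without it was -0.0173. For that list, removing the length trend moved the median from -0.40 (quartiles -0.54 and -0.011) to -0.102 and ended the call. Its score was below every NB-CTRL library in B-CTRL 1 and 2 (-0.085 and -0.72). In B-CTRL 3 (0.27) it was above NB-CTRL 1 and 2 (0.19 and 0.014). A lower level shared by the tested group was thus not shown, and B-CTRL 2 alone, length and testing cannot be told apart.

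Immediate early genes were higher in B-CTRL as a list on average, with NB-CTRL 3 (score 0.15) above B-CTRL 1 and 2 (-0.0060 and -0.10). B-CTRL 3 alone may account for part of this, since the median without it was 0.169 and the call ended. A larger striatal share of the piece may add to it as well: over 6 libraries the list's score and the striatal marker score had r = 0.758 (exact permutation p = 0.0722, adjusted 0.144) and rho = 0.543 (exact permutation p = 0.297, adjusted 0.297), in 1 relation computed, with r = 0.823 in 4 libraries without NB-CTRL 2 and B-CTRL 1. These 4 keep B-CTRL 3, the highest in both scores (0.59 and 0.91), so the relation is not separate from that library. With the striatal score as a covariate the immediate early median was 0.245 and the camera call held (adjusted p = 0.00255). The striatal list's own median went from 0.23 to -0.024, which was fixed in advance because the score is the mean of these same genes. That move does not show how well the covariate removes a striatal share from other genes. The immediate early list did not pass camera with an estimated correlation, with the covariate (adjusted p = 0.496) or without it (0.538). The difference was thus not shown to exceed the spread between libraries. Its call with the preset correlation also ended without NB-CTRL 2 (median 0.14), the library with its lowest score (-0.55), and after removal of the length trend. B-CTRL 3 alone, NB-CTRL 2 alone, locus length, the striatal share and a response to testing cannot be told apart.

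Exchanging libraries between groups gives 10 splits, too few for a share under 0.05. Genes past the threshold numbered 0 in the real split and at most 1 in the others, and genes at an unadjusted p under 0.05 numbered 1730 and at most 1503, with 1 of 10. Functional lists numbered 10 in the real split and at most 10 in the others (2 of 10 splits as many), and marker lists 1 and at most 9 (10 of 10). Other groupings of these libraries thus called more marker lists, and the cause was not tested. Marker lists had estimated correlations up to 0.95 (choroid plexus) against camera's preset of 0.01, and 0 passed with an estimated correlation. The smallest camera p was 0.000269 in the real split and 2.1e-14 in another for immediate early genes (6 of 10 as small), 2.38e-22 and 1.3e-14 for ribosomal proteins (1 of 10), and 2.7e-15 and 1.2e-10 for oxidative phosphorylation (1 of 10).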
